A study of Mus musculus with 48 samples.

How the data were processed

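RNA sequencing libraries of mouse striatum were analysed from the tables deposited with the study. The series description gives 24 mice for the 48 libraries, and each replicate had an IP library (RNA precipitated with the tagged ribosomes of astrocytes) and an input library (RNA of the cleared lysate). The titles name the same mouse for both, except in MPTP replicate 2, and the title of wild-type replicate 3 may join 2 mice, which were treated as 1 replicate. Per the labels, the RiboTag virus was given 3 weeks before RNA extraction, and libraries were made with a stranded, ribosomal RNA-depleting kit and sequenced on a HiSeq4000. Groups were taken from the labels: vehicle and MPTP (20 mg/kg, 4 doses), wild-type littermates and SAPAP3 knockout, and control cargo and hM4Di in R6/2 mice, with 4 replicates each. The labels do not say whether or when an agonist of hM4Di was given, and the treatment text they share describes other perturbations than these.

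Per the submitters' processing notes, reads were aligned with STAR to mm10 and counted with HTSeq, with no versions or gene annotation given. The deposited count table held whole read counts for 24060 gene symbols in the 48 libraries. The deposited FPKM table was, as checked against the counts, each count divided by 1 length per gene and by the column total, so it carried no further normalization by the authors. No column was left unmapped. Symbols in 4 rows were duplicated, and these were kept as separate rows and are not named. The tables held no mitochondrially encoded genes.

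Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr by group (minimum count 10), scaled by TMM and tested with the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Within each experiment, the perturbed group was compared with its control among IP libraries and among input libraries. IP was compared with input over all 16 libraries with the condition in the model, and a gene counted as enriched or depleted when the fold passed 2. The difference between the IP effect and the input effect was tested as an interaction. Log2 fold changes are given with the standard error that the F statistic implies, and CPM are TMM-normalized.

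The 35 gene lists were fixed before the data were examined, as were the groups, comparisons, main tests and the alternatives not named below as added. Lists with at least 3 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data. Members were also adjusted over the list alone. A list mean per library, relative to the control mean, was compared by an exact permutation test of 4 against 4, two-sided, whose smallest p is 0.0286. The named genes followed a rule written before the data were examined. Dlgap3, Rpl22, Chrm4, Th, Slc6a3, Gfap, Slc1a2, Kcnj10, Aldh1l1 and Thbs1 were always eligible. Each IP comparison added the 8 largest rises and 8 largest falls by log2 fold change among genes that passed, with an average log2 CPM of at least 1 and groups that did not overlap, and each input comparison 4 and 4. Each interaction added the 4 smallest p. Where fewer than 5 genes passed, the 5 smallest p were given as not passing. Each list that passed camera or held at least 3 called members added up to 4 members by smallest p, and each cell type list the 4 members with the smallest p in the comparison of IP with input. Gene models without a descriptive symbol were skipped, and the report names a part of the eligible genes; some are not reported here.

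The alternatives were relative log expression and upper-quartile scaling, DESeq2 1.42.0, limma-voom, limma-trend on log2 FPKM with a pseudocount of 1, no filter beyond 1 read, a mean CPM of at least 1, the replicate number as a block, all 16 libraries of an experiment together, an adjusted p threshold of 0.1, Xist and Y-linked genes left out, and each replicate left out in turn. For comparisons across fractions, the animal was used as a block, taken as the replicate number within a condition. Whether IP and input libraries of 1 animal pair was checked by correlating their residuals from the group means. Pairs followed the replicate number, which goes with the animal names in the titles except in MPTP replicate 2. The correlations were 0.387 to 0.636 in the R6/2 experiment and 0.249 to 0.517 in the SAPAP3 experiment, where 8 of 8 libraries matched their own animal best. They were 0.0638 to 0.377 in the MPTP experiment (7 of 8). The pair that did not match best was MPTP replicate 2 (0.0638), whose titles name different animals for IP and input. Alternatives added after the data were seen left out both MPTP replicate 2 libraries, both mice with Xist reads in the SAPAP3 experiment, or hM4Di replicates 2 and 3 together, or used Xist expression as a covariate.

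Gene coordinates came from GENCODE M21 on GRCm38, the assembly of mm10, and were found for 94.6% of the symbols. On simulated counts with the depth and spread of these libraries, edgeR called 77.6%, 67.2% and 65.7% of genes changed 1.5-fold in the MPTP, SAPAP3 and R6/2 IP comparisons, and 97.0%, 95.5% and 94.0% of genes changed 2-fold. For the input comparisons it called 80.6%, 70.1% and 79.1% at 1.5-fold, and for the interactions 62.7%, 43.3% and 59.7%. The changed genes (67 at 1.5-fold) had a mean CPM of at least 1, and libraries were drawn independently, without the pairing of IP and input. Of genes given no change, edgeR called 19, 7 and 12 in the MPTP, SAPAP3 and R6/2 IP comparisons, and DESeq2 47, 32 and 49.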

Results

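Gene expression was measured in the striatum of adult mice (24 by the series description) with RiboTag, a method in which one cell type carries a ribosomal protein with an epitope tag so that its ribosome-bound RNA can be pulled out of a tissue lysate. An adeno-associated virus delivered tagged Rpl22 to striatal astrocytes 3 weeks before RNA was taken, and each replicate had an immunoprecipitated library (IP, astrocyte ribosome-bound RNA) and an input library (RNA of the whole lysate). Both came from the same mouse by the titles, except in MPTP replicate 2, whose titles name different animals. The 48 libraries formed 3 experiments of 16 libraries, each with 4 control and 4 perturbed replicates. The first compared vehicle with 4 doses of 20 mg/kg MPTP, a toxin that kills dopamine neurons. Its labels place the injections in the striatum although the dose is per body weight, so the route is uncertain. The second compared wild-type littermates with SAPAP3 knockout mice, which lack the postsynaptic scaffold gene Dlgap3 and serve as a model of obsessive-compulsive disorder. The third was done in R6/2 mice, a model of Huntington's disease, and compared a control cargo with hM4Di, an engineered Gi-coupled receptor derived from the human M4 muscarinic receptor. The 24 IP libraries held 34.3 M to 61.5 M counted reads (mean 46.7 M ± 6.47 M, SD, n = 24). The 24 input libraries held 21.9 M to 39.0 M (mean 29.6 M ± 4.79 M, SD, n = 24). No pair among the 72 pairs of libraries of the same group agreed within sampling noise, with chi-square per degree of freedom from 3.99 to 91.4.

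The comparison of IP with input asked how far the precipitate represented astrocyte RNA. Astrocyte markers were higher in IP in each of the 3 experiments, and all 28 tested members passed a 2-fold enrichment each time. Their median log2 fold change was 2.36 in the MPTP experiment, 2.21 in the SAPAP3 experiment and 2.31 in the R6/2 experiment. In the MPTP experiment the glutamate transporter genes Slc1a3 and Slc1a2 rose by 2.52 ± 0.042 and 3.21 ± 0.0904 on the log2 scale (± SE, 8 IP and 8 input libraries), the gap junction gene Gja1 by 2.67, the inward rectifier potassium channel gene Kcnj10 by 2.91, Aldh1l1 by 2.56 and the intermediate filament gene Gfap by 2.78. Microglial markers lay at the other end, with all 17 depleted in each experiment and medians of -5.04, -3.87 and -5.01. The fractalkine receptor gene Cx3cr1 was at -5.08 and Tmem119 at -5.25 in the MPTP experiment. Of 16 endothelial and mural cell markers 13 were depleted in each experiment, among them the tight junction gene Cldn5 (-3.75) and Ly6c1 (-3.88) in the MPTP experiment.

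Neuronal and oligodendrocyte RNA was distributed unevenly between the fractions. Medium spiny neuron markers were lower in IP, with medians of -0.87, -0.53 and -0.71 and 23, 22 and 23 of 23 genes passing the test, and Arpp21 and the homeobox gene Meis2 were at -1.83 and -1.24 in the MPTP experiment. Striatal interneuron markers were higher, with 8, 6 and 9 of 11 enriched over 2-fold. Chat, which makes acetylcholine, was at 2.23, 2.50 and 2.48 in the 3 experiments, and in the MPTP experiment the choline transporter gene Slc5a7 was at 2.18 and the nitric oxide synthase gene Nos1 at 2.99. The tyrosine hydroxylase gene Th, on the list of dopamine neuron transcripts, was at 1.54 there. That list had a median of 0.22 in the MPTP experiment, with 2 of 6 genes enriched and 1 depleted. The neuropeptide Y gene Npy was at 2.15 in the R6/2 experiment. Of the 11 ependymal and choroid plexus markers 9 were enriched in each experiment, with the cilia regulator Foxj1 at 2.05 in the MPTP experiment. Oligodendrocyte markers had medians of 0.17, 0.78 and 0.01, with the myelin genes Cnp at 0.68 and Mobp at -0.66 in the MPTP experiment, Cnp at 1.29 and Mag at 1.38 in the SAPAP3 experiment, and Mobp at -1.11 in the R6/2 experiment. Medians of oligodendrocyte precursor markers were 0.07, 0.97 and -1.11, with Sox10 at 1.06 and Olig2 at 1.11 in the SAPAP3 experiment and Pdgfra at -1.92 and Gpr17 at -1.97 in the R6/2 experiment. Rpl22, the gene of the tagged protein, whose reads can include the virus-delivered copy, was at 2.26, 2.80 and 1.92. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which called 13290 of 15862, 12817 of 16059 and 12887 of 15880 genes. Over 2-fold, 1972, 1922 and 1784 genes were enriched and 2231, 2091 and 1961 depleted, and 1361 were enriched and 1246 depleted in all 3 experiments out of 15409 tested in each.

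**Figure D1:**
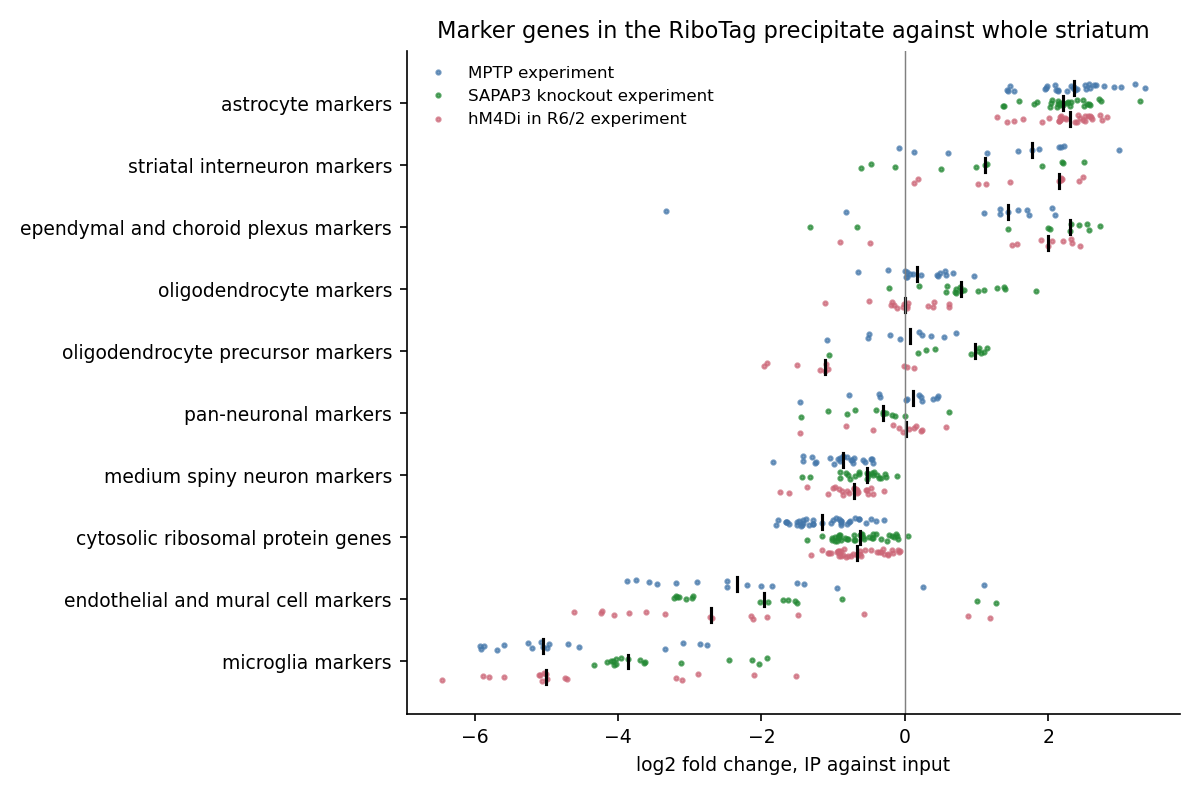
Log2 fold change of IP against input for the genes of 10 lists (vertical axis) in the MPTP, SAPAP3 knockout and R6/2 experiments; each point is a gene and each black bar a list median. Astrocyte markers lie right of 0 with medians of 2.36, 2.21 and 2.31, and microglia markers lie left of 0 with medians of -5.04, -3.87 and -5.01.

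The MPTP experiment asked how astrocyte RNA responds to a toxin given, by the series description, to ablate dopamine neurons. The lesion itself was not measured. In the IP libraries, astrocyte markers were lower in MPTP mice than in vehicle mice, with 26 of 28 genes lower and a median log2 fold change of -0.21. The serine transporter gene Slc7a10 was at -0.41 ± 0.0729 (log2 ± SE, n = 4 per group), the G protein-coupled receptor gene Gpr37l1 at -0.34 ± 0.0692 and the acyl-CoA synthetase gene Acsbg1 at -0.31 ± 0.0671. Transmitter and ion homeostasis genes had a median of -0.20 with 14 of 15 lower, among them the glutamine transporter gene Slc38a3 (-0.38). Cholesterol synthesis genes had a median of -0.17 with 21 of 24 lower, among them Mvd (-0.64), Msmo1 (-0.32) and the sterol sensor gene Insig1 (-0.40). Glucocorticoid response genes pointed the other way with a median of 0.28 and 11 of 14 higher, including the lipid droplet gene Plin4 (1.45), the kinase gene Sgk1 (0.76) and the transcription factor gene Zbtb16 (0.64).

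No single gene of the MPTP IP comparison passed: edgeR's quasi-likelihood test called 0 of 15069 genes. An unadjusted p under 0.05 was found for 1692 genes where chance gives about 753, and DESeq2 called 296 genes, limma-voom 0 and limma on log2 FPKM 0. The 5 genes with the smallest p were Tlcd1 (-0.40), the alanine aminotransferase gene Gpt (-0.47), the splicing kinase gene Clk1 (0.51), Nwd1 (-0.44) and the cholesterol synthesis gene Mvd (-0.64), each with an edgeR adjusted p of 0.0852. The count became 65 without vehicle replicate 2, 14 without MPTP replicate 1 and 1 without MPTP replicate 3. Th was at -0.19 and the dopamine transporter gene Slc6a3 at 0.48 ± 0.399, a gene below 1 CPM here. Gfap was at 0.15, Slc1a2 at -0.28, Kcnj10 at -0.27, Aldh1l1 at -0.22, the thrombospondin gene Thbs1 at 0.56 ± 0.396, Chrm4 at 0.13, Rpl22 at -0.08 and Dlgap3 at 0.00, and none of them passed.

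Adjusted over the list alone, 12 astrocyte markers, 5 transmitter and ion homeostasis genes and 7 cholesterol synthesis genes were lower and 5 glucocorticoid response genes were higher in MPTP IP libraries, against 0 in each list over all genes tested. Camera with a preset correlation called 21 of the 33 lists tested. The adjusted p with an estimated correlation was 0.171 for astrocyte markers, 0.139 for transmitter and ion homeostasis genes, 0.304 for cholesterol synthesis genes and 0.139 for glucocorticoid response genes, so these camera calls were lost there. The mean over the astrocyte markers differed by -0.186 log2 between the groups (SD 0.0933 in vehicle and 0.0651 in MPTP, n = 4 each; exact permutation test, two-sided p = 0.0286, the smallest p that 4 against 4 allows; adjusted p = 0.157 over the lists). All 4 MPTP libraries lay below all vehicle libraries. Microglia markers were higher, with 16 of 17 above 0 and a median of 0.38, among them Tmem119 (0.56) and Itgam (0.66), and their camera call was also lost (adjusted p = 0.139 with an estimated correlation). Pan-neuronal markers had a median of 0.14 with 11 of 12 higher (adjusted p = 0.321 with an estimated correlation). Oligodendrocyte precursor markers had a median of -0.26 with 8 of 10 lower, with Pdgfra at -0.54 and the proteoglycan gene Cspg4 at -0.48 (adjusted p = 0.304 with an estimated correlation). Pan-reactive astrocyte genes had a median of 0.45 with 12 of 13 higher, with the protease inhibitor gene Timp1 at 1.04. Their camera adjusted p was 0.000179, 0.192 without MPTP replicate 1 and 0.422 with an estimated correlation. For list means the exact permutation test (two-sided, n = 4 each) gave p = 0.0286 for the lists of transmitter and ion homeostasis, glucocorticoid response, microglia and pan-neuronal genes. It gave 0.0857 for cholesterol synthesis genes and oligodendrocyte precursor markers, and 0.343 for pan-reactive genes.

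**Figure D2:**
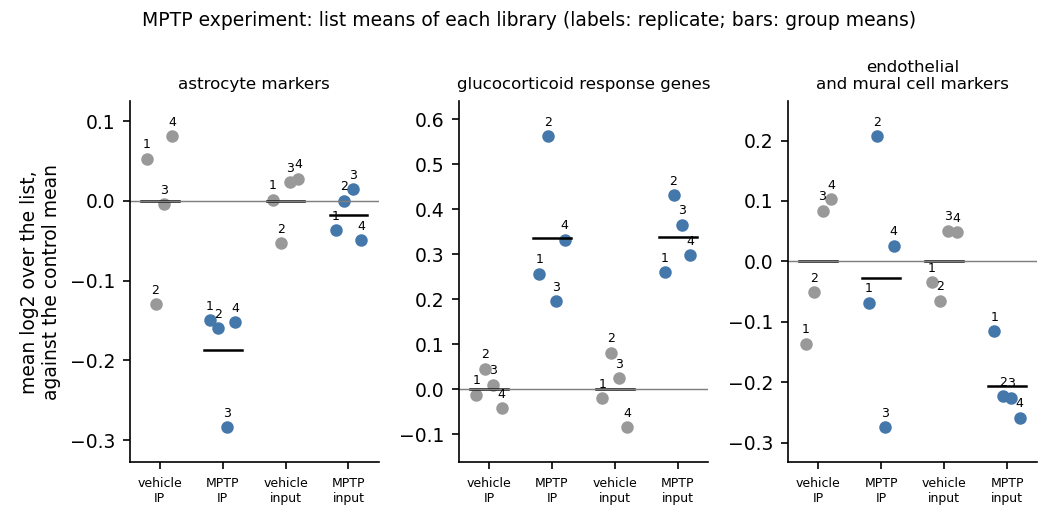
Mean log2 expression over the members of 3 gene lists in each library of the MPTP experiment, relative to the vehicle mean of the same fraction (vertical axis); points are libraries labelled by replicate and bars are group means, n = 4. In IP the astrocyte markers differ by -0.186 and the glucocorticoid response genes by 0.336, and in input the endothelial and mural cell markers differ by -0.206.

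In whole striatum, the input libraries, glucocorticoid response genes were higher in MPTP mice as well. All 14 were higher, with a median of 0.24, and 9 passed when adjusted over the list alone, against 0 over all genes. Plin4 was at 1.21 ± 0.162, the leucine zipper gene Tsc22d3 at 0.42, Sgk1 at 0.41 and the co-chaperone gene Fkbp5 at 0.21 (log2, n = 4 per group). This camera call held with an estimated correlation (adjusted p = 0.0103), and the list mean was higher by 0.338 (exact permutation test, two-sided p = 0.0286, n = 4 each, adjusted p = 0.236 over the lists). Endothelial and mural cell markers were lower, with 15 of 16 below 0 and a median of -0.20, and 7 passed when adjusted over the list alone against 0 over all genes. Cldn5 was at -0.34, the organic anion transporter gene Slco1a4 at -0.29 and the vitronectin gene Vtn at -0.21 (camera adjusted p = 2.14e-12, and adjusted p = 0.0697 with an estimated correlation). Medium spiny neuron markers had a median of -0.08 with 22 of 23 lower, including the transcription factor genes Foxp1 (-0.19) and Bcl11b (-0.15), and adjusted p = 0.199 with an estimated correlation. The exact permutation test (two-sided, n = 4 each) gave p = 0.0286 for the list mean of either. Th was at 0.01 ± 0.108 and Slc6a3 at -0.31 ± 0.321.

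edgeR's quasi-likelihood test called 0 of 15601 genes in these input libraries, with 1289 genes at an unadjusted p under 0.05 where chance gives about 780. DESeq2 called 66, limma-voom 0 and limma on log2 FPKM 0, and the edgeR count was 2 without MPTP replicate 1. The 5 smallest p belonged to Plin4, the integrin gene Itga5 (-0.44), the immediate early gene Egr3 (-0.29), the protocadherin gene Pcdhac2 (-0.24) and the semaphorin gene Sema7a (-0.22), and the lowest edgeR adjusted p was 0.139. Interferon response genes were all 21 higher, with a median of 0.48, but the camera adjusted p went from 0.000164 to 0.461 with the opposite sign without MPTP replicate 1, and was 0.558 with an estimated correlation. The test of whether the MPTP difference itself differed between IP and input called 0 of 15862 genes by edgeR, 0 with the animal as a block and 54 by DESeq2, with 1266 genes at an unadjusted p under 0.05. Its smallest p belonged to Gyk (-0.33), Nwd1 (-0.38), the RNA-binding protein gene Msi2 (-0.38) and Tlcd1 (-0.41), at an edgeR adjusted p of 0.298.

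The knockout experiment asked what the loss of SAPAP3 does to astrocyte and striatal RNA. Its target gene Dlgap3 lies on chromosome 4 from 127169204 to 127237022 (GRCm38, the assembly also called mm10) and was lower in every knockout library than in every wild-type library of the same fraction. In input it went from 416 ± 54.7 CPM in wild type to 182 ± 18.2 CPM in knockout (SD, n = 4 each), a log2 fold change of -1.19 ± 0.101 (SE, edgeR adjusted p = 0.00698), and in IP from 174 ± 26.1 to 65.9 ± 16.3 CPM, a change of -1.40 ± 0.169 (edgeR adjusted p = 0.0283). Reads assigned to Dlgap3 therefore remained in the knockout, and the sources used here do not say which part of the gene was deleted.

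The other 3 genes called in the knockout IP libraries lie within 3.00 Mb of Dlgap3 on the same chromosome. The collagen gene Col16a1 (130047840 to 130099283) rose by 1.38 ± 0.133, the histone deacetylase gene Hdac1 (129516104 to 129542713) was at -1.01 ± 0.12 and the gene model 1700003M07Rik (129960374 to 129963657), named here after its values were seen, was at -1.15. Their edgeR adjusted p were 0.00739, 0.0283 and 0.00739 in that order, with 15198 genes tested and 399 at an unadjusted p under 0.05, fewer than the 760 that chance gives. Within 10 Mb of Dlgap3 lay 251 of the 14457 tested genes with coordinates but 5 of the 7 genes other than Dlgap3 with p under 0.001 (Fisher's exact test, two-sided p = 3.1e-08), and in input 259 of 14834 genes but 9 of 9 (Fisher's exact test, two-sided p = 1.31e-16). The 5 and the 9 both include the 3 called genes that prompted this test. The zinc finger gene Zbtb8a was at -0.77 in IP and -0.81 in input (edgeR adjusted p = 0.373 and 0.0841), and Dcdc2b at -1.82, Hdac1 at -0.92 and Col16a1 at 0.76 in input, where Dlgap3 was the gene called out of 15591 (869 at an unadjusted p under 0.05). The ubiquitin ligase gene Rnf152 (0.38), not on that list of neighbours, had the fifth smallest p in IP among genes with a descriptive symbol. The IP count of 4 became 0 without wild-type replicate 4 and 2 without wild-type replicate 1, 2 or 3 or knockout replicate 2, 3 or 4, and the input count of 1 became 0 without knockout replicate 2, 3 or 4. In IP, leaving out any single library removed the call of Hdac1, and each of those that gave 2 or 0 removed the call of Dlgap3. Without both mice with Xist reads, an alternative chosen after the data were seen, all 4 IP calls and the input call of Dlgap3 were lost, and the replicate block removed the IP calls of Hdac1 and 1700003M07Rik. With Xist expression as a covariate, also chosen afterwards, all 4 IP calls and the input call were kept.

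**Figure D3:**
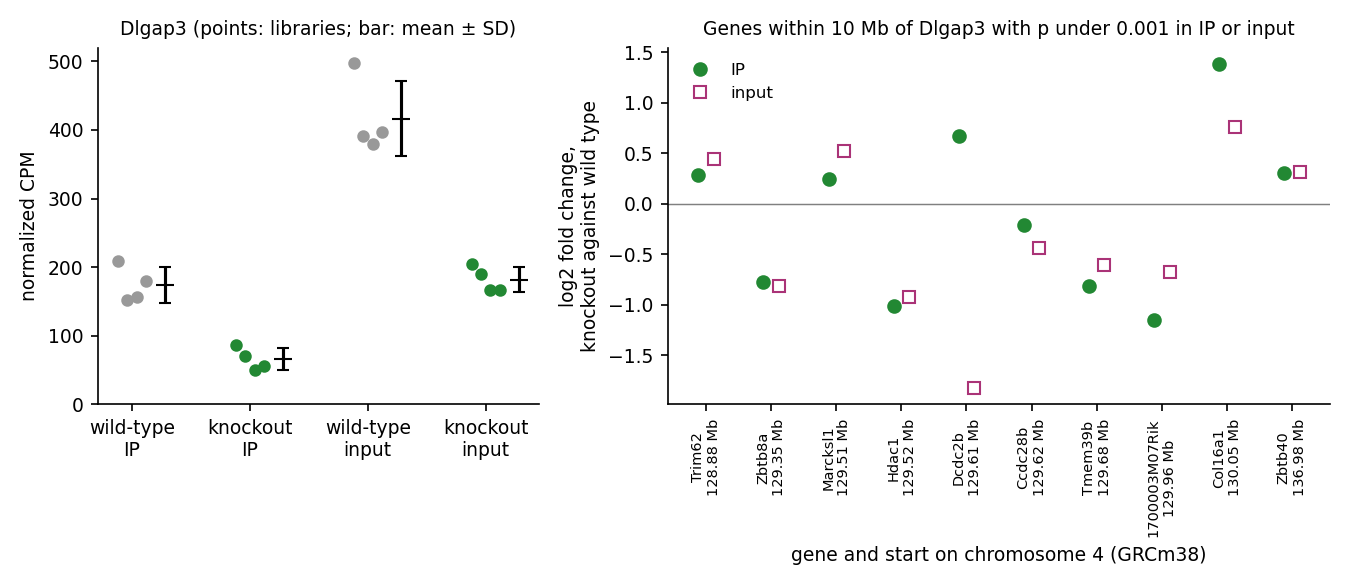
Left, normalized CPM of Dlgap3 in each library (points) with the mean ± SD (n = 4); right, log2 fold change of knockout against wild type in IP (circles) and input (squares) for the 10 genes within 10 Mb of Dlgap3 with p under 0.001 in either fraction, in order of position on chromosome 4. Dlgap3 went from 416 to 182 CPM in input and from 174 to 65.9 CPM in IP, and Col16a1 (1.38 in IP) and Hdac1 (-1.01 in IP) point in opposite directions.

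Among the gene lists, all 23 medium spiny neuron markers were lower in knockout mice in IP and in input, with medians of -0.29 and -0.29. Of these, 1 and 0 passed when adjusted over the list alone and 0 over all genes. The list means differed by -0.286 and -0.274 (exact permutation test, two-sided p = 0.171 and 0.0857, n = 4 each). Against the wild-type mean, knockout IP replicate 1 stood at 0.00, and wild-type replicate 1 at 0.43 in IP and 0.53 in input, with the other wild-type replicates at 0.03 or below, so much of both differences rests on wild-type replicate 1. Sh3rf2 was at -0.56 in both, the adenosine receptor gene Adora2a at -0.48 in IP, and Foxp1 at -0.26 in input. The camera calls were lost (adjusted p = 0.430 in IP and 0.459 in input with an estimated correlation). Immediate early genes, which neuronal activity induces, had a median of -0.24 in IP with 14 of 16 lower and 4 passing when adjusted over the list alone, against 0 over all genes, with Egr2 at -1.35 and Egr4 at -0.73 (adjusted p = 0.187 with an estimated correlation). Glucocorticoid response genes had a median of 0.35 in IP with 13 of 14 higher, 5 of them passing when adjusted over the list alone and 0 over all genes, with Zbtb16 at 0.99 and Hif3a at 0.93 (adjusted p = 0.333 with an estimated correlation). The means of the glucocorticoid response genes were 0.03, 0.27, 0.75 and 0.83 in knockout IP replicates 1 to 4, against the wild-type mean. The exact permutation test gave a two-sided p of 0.0857 (n = 4 each) for the list mean of the immediate early genes and for that of the glucocorticoid response genes.

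Heat shock genes were all 11 higher in knockout IP libraries, with a median of 0.16 and 4 passing when adjusted over the list alone against 0 over all genes, among them the inducible chaperone genes Hspa1a (1.27) and Hspa1b (2.01). Their mean was higher by 0.358 (exact permutation test, two-sided p = 0.0286, n = 4 each, adjusted p = 0.707 over the lists), and the camera call had an adjusted p = 0.333 with an estimated correlation. Endothelial and mural cell markers were all 16 lower in knockout input, with a median of -0.27 and 7 passing when adjusted over the list alone against 0 over all genes, with Cldn5 at -0.48 and the angiopoietin receptor gene Tek at -0.39 (adjusted p = 0.459 with an estimated correlation). Cortical excitatory neuron markers had medians of 0.48 in IP and 0.38 in input with 9 of 10 higher in each. Their camera adjusted p of 0.00122 in IP was 0.0892 without knockout replicate 1. That of 0.00198 in input was 0.0590 without wild-type replicate 1 (adjusted p = 0.450 and 0.623 with an estimated correlation). Against the wild-type mean, wild-type replicate 1 stood at -1.37 in IP and -1.75 in input for this list, and the other wild-type replicates at 0.32 or above (exact permutation test, two-sided p = 0.257 in IP and 0.286 in input, n = 4 each). Pan-neuronal markers were all 12 higher in input, with a median of 0.13 and 0 passing. The list mean was higher by 0.18 (exact permutation test, two-sided p = 0.0286, n = 4 each, adjusted p = 0.236 over the lists; camera adjusted p = 0.000604, and adjusted p = 0.459 with an estimated correlation). That difference rests largely on wild-type replicate 1, at -0.33 against 0.09 or above in the other wild-type libraries and 0.16 to 0.22 in the knockout libraries. Microglia markers had a median of 0.58 in IP, where knockout replicates 1 and 4 stood at 1.19 and 0.95 and replicates 2 and 3 at -0.08 and -0.30. In input, the microglia markers had a median of -0.24, with all 17 lower and Cx3cr1 at -0.30. Their camera adjusted p in IP was 3.43e-06, 0.105 without knockout replicate 1 and 0.507 with an estimated correlation, and in input 0.489 with an estimated correlation. Astrocyte markers had a median of 0.11 in IP with 27 of 28 higher, and a camera adjusted p of 5.15e-05, which was 0.168 without wild-type replicate 1 and 0.517 with an estimated correlation. For list means the exact permutation test (two-sided, n = 4 each) gave p = 0.0286 for endothelial and mural cell markers in input, 0.371 and 0.343 for microglia markers in IP and input, and 0.343 for astrocyte markers in IP. Gfap was at 0.26, Slc1a2 at 0.18, Kcnj10 at 0.28, Aldh1l1 at 0.08, Thbs1 at -0.11, Th at -0.12, Chrm4 at -0.22 and Rpl22 at -0.34 in IP, none of them passing. Camera called 14 of 33 lists in IP and 16 in input with the preset correlation, and 0 and 0 with an estimated correlation. The knockout effect did not differ between IP and input for any gene by edgeR, with 0 of 16059 called, 203 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 with the animal as a block. Dcdc2b (2.50), the melanocortin receptor gene Mc4r (-0.97), the collagen gene Col1a2 (0.75) and the telomerase RNA gene Terc (2.65) had the smallest p, at edgeR adjusted p of 0.410 and above.

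The R6/2 experiment asked how the Gi-coupled receptor hM4Di in striatal astrocytes alters their RNA in a Huntington's disease model. The labels do not say whether an agonist was given, so the groups differ by the cargo, and signalling through the receptor was not measured. Its IP libraries held the most called genes of the 3 experiments, with cytokine, transcription factor and interferon-induced genes among the large rises. Among genes eligible for naming (average log2 CPM of at least 1, groups that did not overlap, a descriptive symbol), the largest rises were those of the smooth muscle calponin gene Cnn1 (6.47 ± 0.612, log2 ± SE, n = 4 per group), the cytokine gene Il11 (5.74 ± 0.84), the transcription factor genes Maff (5.28) and Fosl1 (4.03), the chemerin receptor gene Cmklr1 (5.20), and the interferon-induced genes Ifi27l2a (5.18 ± 1.22), Ifi44 (4.41 ± 1.21) and Oas1a (4.03 ± 1.07). Among hM4Di IP libraries, Cnn1 was at 18.4 CPM in replicate 3 and at most 6.73 CPM in the others. Il11 was at 26.8 CPM in replicate 3 and at most 6.05 CPM in the others. At these levels both folds rest on control values far below 1 CPM. The largest falls among eligible genes were smaller, those of the nephrin gene Nphs1 (-1.11), its partner Kirrel2 (-0.96), Chp2 (-0.92), Shisa2 (-0.91), the Notch target Hes5 (-0.87), the calcium-dependent kinase gene Camk4 (-0.80), the arginase gene Arg2 (-0.77) and Mycl (-0.74). Chrm4, the mouse gene of the receptor from whose human counterpart hM4Di is derived, went from 47.5 ± 11.8 to 751 ± 135 CPM in IP (SD, n = 4 each; log2 fold change 3.98 ± 0.205). In input it went from 54.2 ± 9.22 to 477 ± 84.3 CPM (3.14 ± 0.149).

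Interferon response genes rose in 16 of 21 cases, and all 21 passed when adjusted over the list alone, with a median of 2.76, including Ifitm3 (2.24) and Xaf1 (2.00). Immediate early genes rose in 8 of 16 cases (12 adjusted over the list alone, median 1.48), including the nuclear receptor genes Nr4a1 (3.00) and Nr4a3 (3.79), Btg2 (1.82) and Fos (2.84). Pan-reactive astrocyte genes rose in 5 of 11 cases (9 adjusted over the list alone, median 1.03), with the intermediate filament gene Vim at 1.03, the protease inhibitor gene Serpina3n at 1.44 and the sphingosine receptor gene S1pr3 at 1.91. A1-type reactive genes rose in 7 of 12 cases (8 adjusted over the list alone, median 1.83), among them the complement genes Serping1 (2.15) and C3 (1.86), and A2-type reactive genes in 6 of 10 (7 adjusted over the list alone, median 1.32), among them Cd109 (1.05) and Emp1 (1.75). Cholesterol synthesis genes rose in 7 of 24 cases (16 adjusted over the list alone, median 0.59), with Insig1 at 1.25. The adjusted p with an estimated correlation was 0.445 for interferon response genes, 0.306 for immediate early genes, 0.306 for pan-reactive genes, 0.391 for A1-type genes, 0.408 for A2-type genes and 0.445 for cholesterol synthesis genes, so each camera call was lost there. The exact permutation test gave a two-sided p of 0.0286 (n = 4 each, adjusted p = 0.0629) for the list mean of each of these 6 lists. Over the list of interferon response genes, the mean was 0.90, 2.74, 4.20 and 0.79 log2 above the control mean in hM4Di replicates 1 to 4. For the immediate early genes it was 1.12, 2.42, 1.66 and 0.81.

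Markers of other cells of the striatum moved in opposite directions in the same IP libraries. All 16 oligodendrocyte markers rose (16 adjusted over the list alone, median 0.86), including Mobp (0.81), Mog (0.90) and the transferrin gene Trf (1.08), with adjusted p = 0.306 with an estimated correlation. Of the 10 precursor markers, Sox10 (0.47) and Olig1 (0.61) rose and Pdgfra (-0.65) fell. Medium spiny neuron markers fell in 14 of 23 cases (20 adjusted over the list alone, median -0.46), including Adora2a (-0.63) and Foxp1 (-0.46), with adjusted p = 0.306 with an estimated correlation. Postsynaptic density genes fell in 11 of 16 cases (13 adjusted over the list alone, median -0.34), including the glutamate receptor gene Grin2b (-0.43) and the scaffold genes Dlg2 (-0.31) and Dlg3 (-0.35), and pan-neuronal markers in 5 of 12 (7 adjusted over the list alone, median -0.23), including Nrgn (-0.50) and Camk2a (-0.45). Both had adjusted p = 0.306 with an estimated correlation. Microglia markers had a median of 0.29 with 0 of 16 passing over all genes and 0 adjusted over the list alone. Among ependymal markers 3 of 11 rose (4 adjusted over the list alone), including Foxj1 (0.61) and the tektin gene Tekt1 (0.55).

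Astrocyte markers themselves went both ways, with 2 rising and 4 falling among 28 (3 and 4 adjusted over the list alone), a median of -0.04 and a camera adjusted p of 0.126. Gfap rose by 0.77 ± 0.173, while Slc1a2 (-0.44 ± 0.0493), the glycolytic gene Aldoc (-0.38 ± 0.0635) and the glutamine synthetase gene Glul (-0.39 ± 0.0732) fell. Kcnj10 was at -0.05, Aldh1l1 at 0.28 (edgeR adjusted p = 0.0519), Thbs1 at 1.87 (edgeR adjusted p = 0.0622), Th at 0.71 and Dlgap3 at -0.42, and none of them passed. Rpl22 fell by 0.98 ± 0.216, from 514 ± 157 to 261 ± 26.0 CPM (SD, n = 4 each). Of 26 G protein and calcium signalling genes 3 rose and 6 fell (4 and 8 adjusted over the list alone), with the GABA receptor gene Gabbr1 at -0.54, the phospholipase gene Plcb1 at -0.35, the signalling regulator gene Rgs4 at -0.52 and the lysophosphatidic acid receptor gene Lpar1 at 1.04. Astrocyte-secreted genes included Mertk (-0.50), a phagocytic receptor gene that fell, and Thbs2 (0.67), which rose. Of 37 cytosolic ribosomal protein genes 6 rose, among them Rps4x (0.33), with a camera adjusted p of 0.0141 that was 0.0860 without hM4Di replicate 3, and adjusted p = 0.591 with an estimated correlation. Of 14 clock genes 1 rose, Per1 (0.73), and 5 fell, among them Nr1d1 (-0.62) and Arntl (-0.36), with adjusted p = 0.306 with an estimated correlation. Nr4a2 (2.57), on the list of dopamine neuron transcripts and also induced by activity in other cells, the stress response gene Atf3 (3.48) and the laminin gene Lamb2 (0.30) also rose.

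In all, edgeR's quasi-likelihood test called 2227 of 15159 genes in the R6/2 IP libraries, of which 1374 rose and 853 fell, and 274 rose and 12 fell over 2-fold. Upper-quartile normalization gave 1221 rises and 1190 falls, 50.6% rises against 61.7%, and limma on log2 FPKM 1545 rises and 516 falls. The count was 892 without control replicate 1, 1409 without control replicate 4 and 1084 without hM4Di replicate 2, and 464 without hM4Di replicates 2 and 3 together, an alternative chosen after the data were seen, of which 444 were among the 2227. Of the 65 called genes named for this comparison, 21 lost their call without control replicate 1 and 20 without hM4Di replicate 2, Gfap and Rpl22 among both, and 7, 13 and 16 lost it without control replicates 2, 3 and 4 and 3, 8 and 1 without hM4Di replicates 1, 3 and 4. Without hM4Di replicates 2 and 3 together 31 lost it, by limma-voom 8, by limma on log2 FPKM 6 and with the replicate block 5. Col16a1, Ifi44, Oas1a and Serping1 lost it without each of the 4 control replicates in turn and without hM4Di replicate 2 or 3, and Gfap also without control replicate 4. Ifi27l2a lost it without each of the 4 control replicates and without hM4Di replicate 2, and by limma-voom and limma on log2 FPKM.

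**Figure D4:**
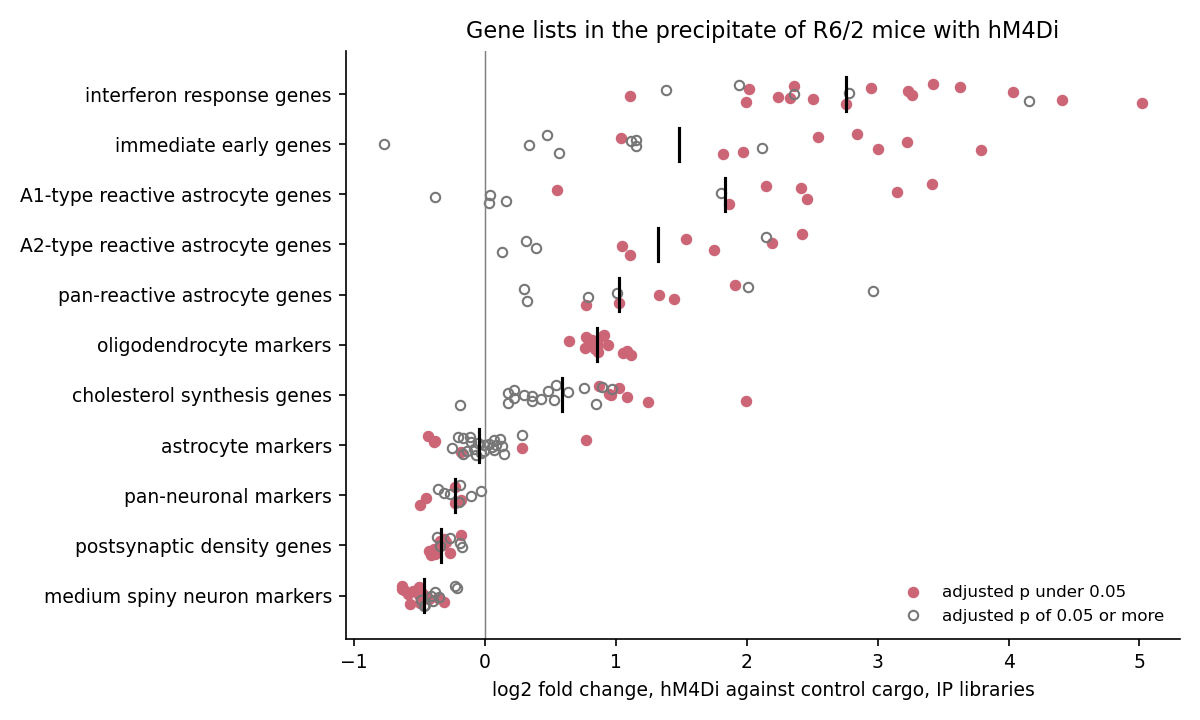
Log2 fold change of hM4Di against control cargo in IP libraries for the tested genes of 11 lists (vertical axis); filled points have an edgeR adjusted p under 0.05, open points do not, and black bars are list medians. All 16 oligodendrocyte markers rose with a median of 0.86, and medium spiny neuron markers had a median of -0.46.

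In whole striatum of the same R6/2 mice, few genes passed. Chrm4 rose by 3.14 ± 0.149, the small GTPase gene Gem by 2.74 ± 0.216 and the matricellular gene Cyr61 by 2.21 ± 0.215, and these 3 of 15168 genes were called by edgeR's quasi-likelihood test, with 1162 at an unadjusted p under 0.05. Fam167a (1.25) and the thyroid hormone deiodinase gene Dio2 (0.58) had the next smallest p, with edgeR adjusted p of 0.0790 and 0.0977. Interferon response genes had a median of 1.67 with all 21 higher and 19 passing when adjusted over the list alone, against 0 over all genes, with Ifit1 at 3.09 ± 0.876 and Oasl2 at 2.89 ± 0.781 (adjusted p = 0.209 with an estimated correlation). Microglia markers had a median of 0.24 with 7 of 17 passing when adjusted over the list alone and 0 over all genes, including the complement gene C1qc (0.81) and the cytokine receptor gene Csf1r (0.29), and the antigen presentation gene Cd74 was at 1.45 (adjusted p = 0.209 with an estimated correlation for microglia markers). Immediate early genes had a median of 0.79 with 4 passing when adjusted over the list alone and 0 over all genes, with Btg2 at 0.86 and Fos at 2.07 (adjusted p = 0.333 with an estimated correlation). The list means of the interferon response genes were 0.22, 1.67, 3.10 and 0.44 in hM4Di input replicates 1 to 4 and those of the immediate early genes 0.05, 1.89, 0.26 and 0.23. The exact permutation test (two-sided, n = 4 each) gave p = 0.0857 and 0.229 for these lists and 0.0571 for microglia markers. Oligodendrocyte markers had a median of -0.02 and medium spiny neuron markers of 0.02, with 0 passing in either. Gfap was at 0.58, Slc1a2 at -0.19 and Rpl22 at -0.30 in input.

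**Figure D5:**
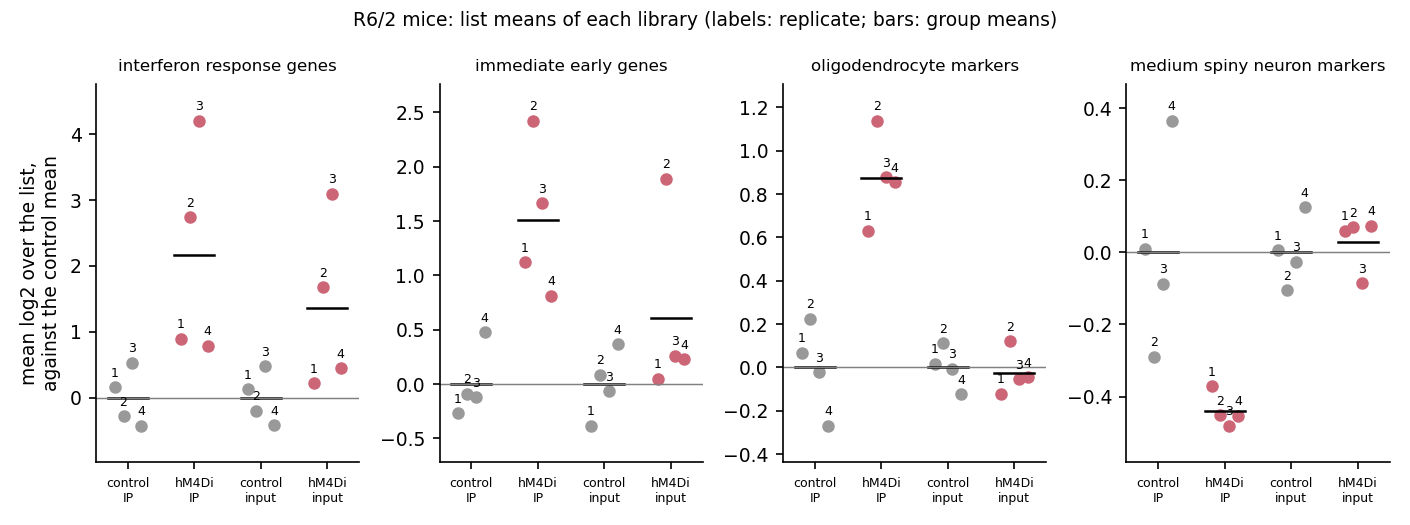
Mean log2 expression over the members of 4 gene lists in each library of the R6/2 experiment, relative to the control mean of the same fraction (vertical axis, with its own scale in each panel); points are libraries labelled by replicate and bars are group means, n = 4. Interferon response genes reach 4.20 in IP and 3.10 in input of hM4Di replicate 3, and oligodendrocyte markers average 0.875 above the control mean in IP.

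The effect of hM4Di differed between IP and input for 492 of 15880 genes by edgeR without an animal block, the test fixed beforehand. Of these, 302 were higher and 190 lower in IP relative to input. With the animal as a block, which the shared mouse of each IP and input library warrants, 2760 genes were called, 1326 higher and 1434 lower, the 492 included, and DESeq2 without the block called 1147. The actin-binding gene Cnn2 (2.55 ± 0.294), Gabbr1 (-0.48 ± 0.0575), Cmklr1 (4.55 ± 0.567) and the splicing regulator gene Ptbp1 (1.24 ± 0.158) had the smallest p, each at an edgeR adjusted p of 0.00288. The oligodendrocyte markers Mog (1.00) and Trf (1.05) and the medium spiny neuron marker Foxp1 (-0.49) were among the 492. The relative log expression scaling without the block gave 294 higher and 280 lower. The balance of higher and lower genes thus depended on the block and on the scaling. In the fit without the block, the count was 91 without control replicate 1, 208 without control replicate 3, and 323, 202, 280 and 128 without hM4Di replicates 1, 2, 3 and 4.

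Genes called in more than 1 experiment were few. In IP libraries the MPTP experiment shared 0 called genes with either of the others by edgeR, since it called none; DESeq2 gave 1 shared with SAPAP3 and 53 with R6/2. The SAPAP3 and R6/2 experiments shared 1 gene with the same sign, Col16a1 (1.38 and 0.45, named in the latter after its values were seen), where independent lists of that size would share 0.264 with the same sign. Fisher's exact test, which counted genes called in both whatever their sign, gave a two-sided p of 0.477. Across genes, which are not independent replicates, Spearman's rho of the log2 fold changes in IP was 0.0403 between MPTP and SAPAP3, -0.0236 between MPTP and R6/2 and 0.111 between SAPAP3 and R6/2.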

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

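Results were examined more closely where a library lay far from the other 3 of its group or where an effect differed between IP and input. Of the tests in this part, those of genes near Dlgap3, of a lower astrocyte share in the MPTP precipitates (with the precursor gap) and of a lower astrocyte share in the hM4Di precipitates were chosen only after the result was seen, and those of RNA from other cells and of time of day in the R6/2 experiment were written before.

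The genes called in hM4Di IP libraries could come from astrocytes or from a changed mix of RNA in the precipitate. Chance is unlikely for the IP count: 1 of the 35 splits of the 8 IP libraries, the real split, called as many genes (2227, highest other 2). That is the smallest share that 35 splits allow, and the split tests here and below were not adjusted for their number. The same held for the difference between the fractions without an animal block (1 of 35, 492 against 1). The input count (1 of 35, 3 against 2) passes only with Chrm4, whose reads may be those of the receptor itself, and decides little. A lower share of astrocyte RNA would raise oligodendrocyte and medium spiny neuron markers both if these cells carry over alike. Relative to input the oligodendrocyte markers went up and the medium spiny neuron markers down, a gap of 1.37 log2 (SD of the gap 0.283 in control and 0.15 in hM4Di libraries, exact permutation test, two-sided p = 0.0286, the smallest possible with n = 4 each). A joint rise was thus not seen. These lists were picked after they had been seen to move apart, so this test decides nothing. Relative to input, astrocyte, microglia and endothelial and mural cell markers changed by -0.00747, -0.0459 and 0.0129 (exact permutation test, two-sided p = 0.971, 0.714 and 0.886, n = 4 each). A lower astrocyte share would lower the astrocyte markers and raise the microglia and endothelial and mural cell markers, and neither was seen. Pan-neuronal markers were lower relative to input (-0.255) and oligodendrocyte markers higher (0.889). The rise of oligodendrocyte markers goes with a lower astrocyte share, which therefore stays open. Another time of day was predicted to move at least 3 of Dbp, Per1, Per2, Per3, Nr1d1, Nr1d2, Ciart and Tef in 1 direction. At most 1 of them was called in a given direction (Per1 up and Nr1d1 down), so the prediction was not met. Genes that miss the threshold with n = 4 may still have shifted. Arntl (-0.36) and Npas2 (-0.50) fell, and the clock list mean differed by -0.163 (exact permutation test, two-sided p = 0.0286, n = 4 each). The test therefore cannot weigh against another time of day. Another share of RNA from other cell types cannot be told apart from a response of the astrocytes. Over the called genes the change went with enrichment in IP (Spearman's rho 0.468, and 0.298 over all genes). A lower astrocyte share would give the opposite sign. That enrichment was computed from libraries that include the hM4Di ones, so the test decides nothing. The effect of the receptor in the R6/2 mice stays open.

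In the SAPAP3 knockout, the called genes other than Dlgap3 were its neighbours. The counts of 4 in IP and 1 in input were each reached by 1 of 35 splits (highest other 0 and 0). Both include Dlgap3, the targeted gene and the only gene in input, so these counts in part restate the genotype and decide little about chance. As many genes at an unadjusted p under 0.05 as the 399 in IP and 869 in input were reached by 25 and 7 of 35 splits (highest other 1876 and 1803). Of 7 genes in IP with p under 0.001, 5 lay within 10 Mb, where 0.122 would be expected (Fisher's exact test, two-sided p = 3.1e-08), and no other 20 Mb stretch held more than 1. The 5 include the called neighbours Col16a1, Hdac1 and 1700003M07Rik that prompted the test, so its p in part restates them. A candidate explanation is that the knockout mice carry alleles of another strain beside the targeted gene, which would give rises and falls alike, and Col16a1 (1.38) and Hdac1 (-1.01) show both. An effect of the deletion itself on neighbouring genes, and a response to the loss of SAPAP3, were not tested and stay open.

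In the MPTP IP libraries, astrocyte markers were lower. The count of 0 genes by edgeR (1692 at an unadjusted p under 0.05, 296 by DESeq2, 0 by limma-voom and 0 by limma on log2 FPKM) was reached by all 35 of 35 splits (highest other 1), as any split reaches 0, and 1692 genes at p under 0.05 by 3 of 35 (highest other 2353), so chance cannot be excluded for the genes. For the 21 lists the rule was met (1 of 35), but only by a margin of 1 list (highest other 20), and with an estimated correlation camera called 0 lists. Chance is therefore not excluded for the lists either. Over all genes the change in IP went against enrichment in IP (Spearman's rho -0.301). A lower share of astrocyte RNA would give this sign, but both values came from the same IP libraries, so the rho decides nothing alone. In the levels relative to input given next, MPTP replicate 2 joins IP and input of different mice by the titles, so its difference is not within 1 mouse. A lower share of astrocyte RNA would raise the markers of the other cell types, and relative to input the 7 lists that lay below input in vehicle mice were higher in 6 cases, by 0.151 log2 on average (SD 0.0936 in vehicle and 0.222 in MPTP, exact permutation test, two-sided p = 0.257, n = 4 each, with pan-neuronal 0.222 at p = 0.0286 and microglia 0.251 at p = 0.0571), as were oligodendrocyte (0.171) and ependymal (0.0971) markers, while oligodendrocyte precursor (-0.328, exact two-sided p = 0.0857) and striatal interneuron markers (-0.117) were lower. Lower levels of the astrocyte marker RNAs in astrocytes would lower them in input too. There their mean differed by -0.0178 (SD 0.0373 in vehicle and 0.03 in MPTP, exact permutation test, two-sided p = 0.486, n = 4 each). Relative to input it differed by -0.178 (exact permutation test, two-sided p = 0.0286, n = 4 each). This argues against lower levels of the 28 markers as the source of the fall in IP. A lower share cannot be told apart from less ribosome-bound RNA per astrocyte. Pan-neuronal and microglia markers go with that share and precursor markers against it. Both the mean shift and the gap between the 7 lists and the precursor list (0.479, SD 0.218 in vehicle and 0.434 in MPTP, exact permutation test, two-sided p = 0.143, n = 4 each) lie within the spread of the libraries. An effect of MPTP stays open as the biological explanation.

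For the other comparisons, a count of 0 genes by edgeR, which any split reaches, says nothing about chance: MPTP input (66 by DESeq2, 0 by limma-voom and 0 by limma on log2 FPKM; 35 of 35 splits, highest other 1), the MPTP difference between fractions (54 by DESeq2; 35 of 35, highest other 0) and the SAPAP3 difference between fractions (1 by DESeq2; 35 of 35, highest other 0). By the number of genes at an unadjusted p under 0.05, chance could not be excluded for MPTP input (1289, 5 of 35, highest other 2071) or the SAPAP3 difference (203, 24 of 35, highest other 680), and for the MPTP difference 1 of 35 splits, the real one, had as many (1266, highest other 1040). For the numbers of lists, it could not be excluded in MPTP input (20 lists, 3 of 35, highest other 21), SAPAP3 IP (14, 16 of 35, highest other 18), SAPAP3 input (16, 6 of 35, highest other 18), hM4Di IP (14, 14 of 35, highest other 19) or hM4Di input (14, 8 of 35, highest other 19). For IP against input chance is unlikely, with 1 of 50 splits each (13290 against 11015, 12817 against 10143 and 12887 against 10602).

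A library lay far from the other 3 in 37 of 390 groups. About 1 in 20 would be flagged among independent, normally distributed values. The genes named here share libraries and were picked by their effects, so the number 37 tests nothing. The ratio given is the gap to the nearest library over the whole range, set against Dixon's 95% critical value. In the MPTP experiment it was 0.834 for Slc6a3 in vehicle IP replicate 2, 0.963 for Thbs1 in MPTP IP replicate 2 (5.03 against 1.68 CPM), 0.883 for Zbtb16 in vehicle IP replicate 2, 0.83 for Insig1 in MPTP IP replicate 1, 0.873 for Plin4 in vehicle input replicate 2, 0.914 for Tsc22d3 in vehicle input replicate 4 (lowest), 0.858 for Tsc22d3 in MPTP input replicate 1 (lowest), 0.917 for Slco1a4 in vehicle input replicate 4 (lowest), and 0.922 for the mean of the astrocyte markers in MPTP IP replicate 3 (-0.28 against -0.16). In the SAPAP3 experiment it was 0.92 for Rpl22 in wild-type IP replicate 2 (1697 against 785 CPM), 0.843 for Adora2a in wild-type IP replicate 1, 0.931 for Hspa1a and 0.86 for Hspa1b in wild-type IP replicate 4, 0.855 for Dlgap3 in wild-type input replicate 1, 0.948 for Cx3cr1 in knockout input replicate 2, and 0.948 for the mean of the medium spiny neuron markers in knockout IP replicate 1 (0.00 against -0.37). Wild-type replicate 1 was lowest for the mean of the cortical excitatory neuron markers in IP (0.852) and input (0.924) and for that of the pan-neuronal markers in input (0.925).

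In the R6/2 experiment, hM4Di IP replicate 3 was highest for Cnn1 (0.838), Il11 (0.864), Maff (0.933), Ifi44 (0.831), Th (0.939), Thbs1 (0.87), Nr4a3 (0.919), Nr4a2 (0.96) and Insig1 (0.873). These values come from 1 library and are not independent. The ratio was 0.852 for Aldoc in hM4Di IP replicate 1, 0.85 for Mobp and 0.846 for Chrm4 (lowest, 550.2 against 792.9 CPM) in hM4Di IP replicate 2, 0.902 for Foxj1 in hM4Di IP replicate 4 (lowest), 0.863 for Shisa2 in control IP replicate 4, 0.909 for C3 in control IP replicate 2, and 0.889 for Fos in hM4Di input replicate 2. For the immediate early gene mean in hM4Di input replicate 2 it was 0.885 (1.89 against 0.26), and for the medium spiny neuron marker mean in hM4Di input replicate 3 it was 0.913 (lowest).

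The effect of hM4Di differed between IP and input, by the interaction test without an animal block, for 492 genes. Among those named in the report the difference was 2.55 for Cnn2, -0.48 for Gabbr1, 4.55 for Cmklr1, 1.24 for Ptbp1, -0.49 for Foxp1, -0.55 for Nrgn, 2.50 for Nr4a2, 0.73 for Mobp, 1.00 for Mog, 1.05 for Trf, 0.74 for Sox10, 2.60 for Nr4a3, 0.96 for Lpar1, -0.36 for Plcb1, -0.45 for Grin2b, -0.29 for Dlg2 and -0.36 for Dlg3. Of these 17, 9 lost their call without control mouse 1 and 6, 4, 4, 6, 4 and 6 without control mice 3 and 4 and hM4Di mice 1, 2, 3 and 4. With the animal as a block 0 of the 17 lost it.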

How the results depend on the processing

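The alternatives that left out 2 replicates together, or used Xist as a covariate, were chosen after the data were seen. Without other mention, the cause of a moved value was not tested.

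By DESeq2, MPTP gave 296 genes in IP, 66 in input and 54 for the difference between fractions (0 each by edgeR, with 1692, 1289 and 1266 at an unadjusted p under 0.05), SAPAP3 11, 8 and 1 (4, 1 and 0 by edgeR) and hM4Di 3467, 57 and 1147 (2227, 3 and 492). All 16 libraries together gave 289 for MPTP IP, 3 for SAPAP3 input and 3636 for hM4Di IP. An adjusted p threshold of 0.1, which admits more genes by construction, gave 50 for MPTP IP, 2 for SAPAP3 input, 3728 for hM4Di IP and 5 for hM4Di input. Without a filter, MPTP input had 1 and hM4Di input 5. The replicate block gave 1 for MPTP input, 2 for SAPAP3 IP and 6 for hM4Di input, although control and perturbed libraries of the same number do not pair (correlations -0.388 to 0.433). The animal block gave 2760 for the hM4Di difference between fractions. Without both Xist-positive mice, SAPAP3 IP and input had 0 and 0. With Xist as a covariate, none of the genes called there in the main test lost its call. Without hM4Di replicates 2 and 3, hM4Di IP had 464 and input 5. Shared IP calls were 1 for MPTP and SAPAP3, 53 for MPTP and hM4Di and 3 for SAPAP3 and hM4Di by DESeq2, and 7 for MPTP and hM4Di and 2 for SAPAP3 and hM4Di at a threshold of 0.1. With an estimated correlation, camera called 0, 1, 0, 0, 0 and 0 lists for MPTP IP and input, SAPAP3 IP and input and hM4Di IP and input (21, 20, 14, 16, 14 and 14 at the preset correlation). The counts by relative log expression and upper-quartile scaling, limma-voom, limma on log2 FPKM and a mean CPM filter stayed within 1.5 times the main counts, as did every alternative run for IP against input.

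Leaving out each replicate gave 0 to 65 genes for MPTP IP, 0 to 2 for MPTP input, 0 to 0 for the MPTP and SAPAP3 differences between fractions, 0 to 3 for SAPAP3 IP, 0 to 1 for SAPAP3 input, 892 to 2130 for hM4Di IP, 3 to 4 for hM4Di input and 91 to 434 for the hM4Di difference between fractions. For IP against input it gave 13051 to 13170, 12391 to 12864 and 12556 to 12904, and for lists 17 to 23 and 16 to 22 (MPTP IP and input), 10 to 18 and 11 to 18 (SAPAP3), and 13 to 16 and 13 to 17 (hM4Di).

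No named gene that passed changed sign under these alternatives. Among those not passing, Dlgap3 in MPTP IP (0.00) was at -0.00685 by limma-voom, -0.000701 without a filter, -0.00646 with the replicate block, -0.0115 with all 16 libraries, -0.0109 and -0.00897 without vehicle replicates 1 and 2, -0.0353 and -0.0691 without MPTP replicates 2 and 3 and -0.0471 without both replicate 2 libraries, with a highest value of 0.0811 without MPTP replicate 1. In MPTP IP, Rpl22 was at 0.0246 without MPTP replicate 3 (lowest -0.18 without MPTP replicate 1), Gfap at -0.0641 without MPTP replicate 1 (highest 0.26), and Thbs1 at -0.0243 without MPTP replicate 2 and -0.128 without both replicate 2 libraries (highest 0.72 without MPTP replicate 3). Th in MPTP input was at -0.0499 and -0.0369 without vehicle replicates 1 and 2, -0.0427 without MPTP replicate 1 and -0.00821 without both replicate 2 libraries (highest 0.0754 without vehicle replicate 3). In SAPAP3 IP, Rpl22 was at 0.0512 without wild-type replicate 2 (lowest -0.63), Aldh1l1 at -0.000632 without wild-type replicate 1 (highest 0.15), and Thbs1 at 0.0158 without wild-type replicate 4 and 0.0380 without both Xist-positive mice (lowest -0.21). Kcnj10 in hM4Di IP was at 0.0481 without control replicate 3, 0.0581 and 0.0619 without hM4Di replicates 2 and 3 and 0.26 without both (lowest -0.18 without hM4Di replicate 1).

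Of simulated 1.5-fold changes edgeR called 43.3% to 80.6% in the comparisons of perturbed with control mice, and 95.5%, 82.1% and 88.1% for IP against input. Depth was not varied. The share was 79.1% in R6/2 input (21.9 M to 28.0 M reads per library) and 65.7% in R6/2 IP (46.0 M to 54.5 M). These fractions can also differ in spread, and the changed genes were drawn separately for each. The values therefore do not show how the share depends on depth.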

Other observations

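Rpl22 reads in the precipitates can include reads of the virus-delivered tagged gene as well as of the endogenous one, and so differ with the dose of virus. In IP libraries Rpl22 stood at 514 ± 157 CPM in R6/2 control and 261 ± 26.0 CPM in hM4Di mice (SD, n = 4 each), with 1697 CPM in wild-type replicate 2 of the SAPAP3 experiment. Chrm4 was at 3.98 log2 in hM4Di IP and 3.14 in hM4Di input. Whether these Chrm4 reads came from the human-derived transgene was not tested, since the tables hold no read sequences.

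Cytosolic ribosomal protein genes were lower in IP than in input in 37, 33 and 31 of 37 cases in the MPTP, SAPAP3 and R6/2 experiments, with medians of -1.15, -0.63 and -0.67. Fibroblast and meningeal markers had medians of -1.97, -1.87 and -2.01.

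In the MPTP IP libraries, respiratory chain genes had a median of -0.08 with 34 of 35 lower (adjusted p = 0.422 with an estimated correlation), heat shock genes a median of 0.20 with 11 of 11 higher (adjusted p = 0.410 with an estimated correlation) and interferon response genes a median of 0.31, whose camera call held in 4 of the 8 cases with a library left out (adjusted p = 0.772 with an estimated correlation). In SAPAP3 input, cholesterol synthesis genes had a median of 0.15 with 23 of 24 higher, and in hM4Di input a median of 0.15 with 24 of 24 higher (adjusted p = 0.459 and 0.322 with an estimated correlation).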
